A study of Mus musculus with 15 samples.

How the data were processed

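RNA from c57bl/6 mouse embryonic fibroblasts, labelled WT or NSD2 KO and grown in DMEM with donor bovine serum, was taken up in TRIzol, made into libraries with the NuGEN Ovation SP Ultralow kit on a Mondrian SP and sequenced in pairs of reads on a HiSeq2000, per the labels' protocols. The deposited values were raw counts of reads per gene symbol, 1 table per library. Per the submitters' processing notes, bcl2fastq 2.15, STAR 2.5.2b, HTSeq and the mm9 build were used. The annotation, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes are uncertain, and so are near-identical copies such as Gbp6 and Gbp10, Tgtp1 and Tgtp2, Oas1a and Oas1g, Ifit3, Trim30 and the H2 genes, whose shared reads HTSeq could leave out or split.

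Each table listed 24015 genes. The 5 HTSeq summary lines were left out of library sizes and tests. Reads in no gene made up 35.1% to 41.3% of the uniquely aligned reads and ambiguous ones 0.393% to 0.496%, and there were 1.16 to 1.88 alignments counted as not unique per gene count. Between 14902 and 16255 genes were detected per library. Replicates were compared before averaging, and no pair agreed within sampling noise (chi-square per degree of freedom 3.74 to 178, or 1.97 to 5.05 without Rn45s and Lars2). The labels name no separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

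Counts were scaled by TMM (factors 0.895 to 1.22) in edgeR 4.0.16 under R 4.3.3. Genes passing filterByExpr with a minimum count of 10 (13802) were tested with edgeR's quasi-likelihood test in a model of 8 groups over all 15 libraries, with 7 residual degrees of freedom, and Benjamini-Hochberg adjusted p below 0.05 was called. KO naive 2 h has 1 library, which was assumed to vary like the other groups. There were 13 comparisons, made of interferon against none, pretreated against naive, restimulation, KO against WT, and genotype differences of these. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 312 tests of 24 lists. Of 125 calls, 66 held with an estimated correlation. The 25 lists held interferon-related genes (antiviral, GTPase, MHC class I, signalling, sensor and chemokine lists), H3K36 methylation and H3.3 deposition, cell cycle, p53, extracellular matrix, contractile, immediate early, Hox, patterning, imprinted, cholesterol, ER stress and sex-linked genes, and markers of macrophages and blood, endothelium, epithelium, skeletal muscle, nerve and glia, adipocytes, and cartilage and bone. The sex-linked list had too few measured members for a test.

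Genes were named by a fixed rule. It takes Whsc1 in every library, and per comparison the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap (for genotype differences, among called genes). It also takes up to 4 members of each list with the smallest p, and 15 interferon-stimulated genes followed through all groups. Some genes that this rule takes are not reported here. The comparisons, their tests, lists, this rule and all alternatives except the pair named below were fixed before the data were examined, unlike some tests of explanations. A fold against a side with no count is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval. Intervals and floors cover counting error only.

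Alternatives were RLE size factors, no filter, DESeq2 1.42.0, a fit on the compared groups, a replicate block, an estimated correlation and leaving out each library. Leaving Rn45s and Lars2 out of the counts, and leaving out the 3 libraries low in them, were chosen after seeing the data. The steps were tested on simulated counts with 200 changed genes, 100 per size. For interferon in WT naive cells (13380 genes) 99% of changes of 1 log2 unit and 100% of 2 were recovered, with 4.33% of calls false. In KO (13353 genes) the shares were 93%, 100% and 5.85%, for KO against WT at naive 0 h (13370 genes) 95%, 100% and 8.02%, and for the genotype difference (13338 genes) 90%, 100% and 6.40%. Gene order came from GRCm38.p6, used for neighbours alone. Figures were drawn with matplotlib 3.10.9.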

Results

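RNA was sequenced from mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, labelled wild type (WT) or knockout (KO) for NSD2. NSD2, listed in the files under its older symbol Whsc1, is an enzyme that methylates lysine 36 of histone H3. Cells were naive, or had been pretreated with interferon beta for 3 h, washed and kept for 24 h without it. Each kind was sampled at 0 h and after 2 h with 100 units per ml of interferon beta. This gave 8 groups of 2 libraries, or 1 for KO naive 2 h, 15 in all. The design asks whether earlier interferon alters the later response, and whether NSD2 bears on it. The libraries held 17170845 to 44116418 counts in genes, with a median of 28585502. The ribosomal transcript Rn45s and Lars2 together took 10.6% to 29.4% of these counts, and 3 libraries lay below 20% (WT naive 0 h replicate 1 at 10.6%, WT pretreated 2 h replicate 1 at 18.5% and KO pretreated 0 h replicate 2 at 19%). Values below are counts scaled to library size (CPM) as mean ± SD, and fitted log2 changes ± SE; medians of lists are log2 changes.

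The targeted gene, Whsc1, was still counted in every library. WT naive libraries held 108.5 to 115.5 CPM, WT pretreated libraries 133.1 to 146.2 CPM and KO libraries 95.7 to 110.5 CPM. Averaged over the 4 conditions, Whsc1 was lower in KO by a log2 change of -0.28 ± 0.025 (edgeR adjusted p = 2.0e-11), and at naive 0 h by -0.18 ± 0.047 (adjusted p = 0.0013). A count over the whole gene does not check a deletion of part of it, so WT and KO below stand for the labels of the libraries.

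Genotype set the libraries apart most, then interferon. The first principal component of log2 CPM held 75.4% of the variance and separated KO from WT, and the second held 13.3% and separated 2 h from 0 h. The single KO naive 2 h library lay nearest the KO pretreated libraries at 2 h.

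**Figure D1:**
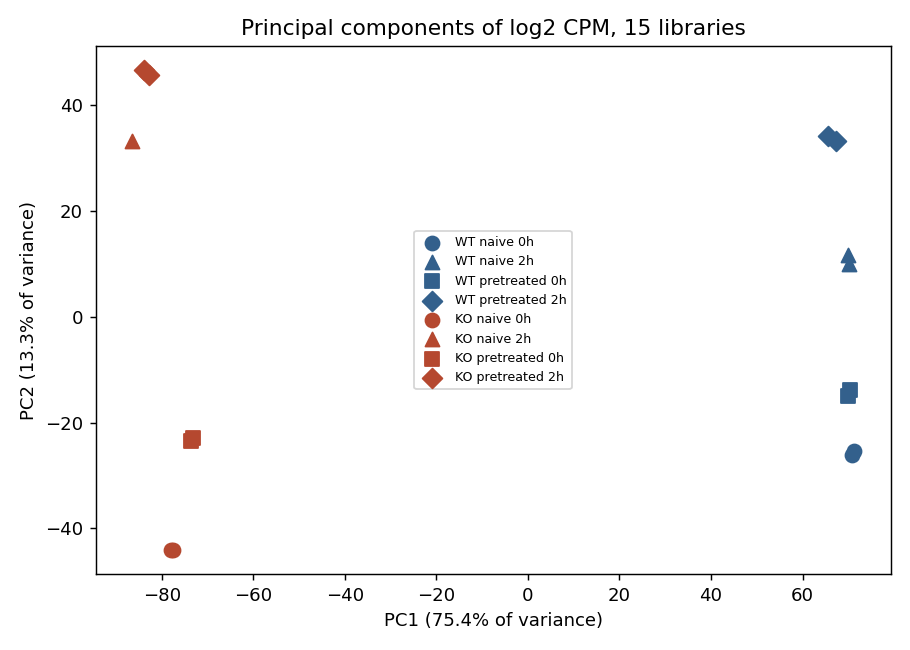
First (75.4% of the variance, horizontal) and second (13.3%, vertical) principal components of log2 CPM for the 15 libraries. Each point is 1 library, with colour and shape by group. KO and WT libraries sit at opposite ends of the first component, and libraries at 0 h and 2 h part along the second.

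In naive WT cells, 2 h of interferon beta raised antiviral transcripts from a low base. Usp18, a protease that removes the ubiquitin-like protein ISG15 and restrains the interferon receptor, rose 60.1-fold from 0.350 ± 0.0773 CPM to 19.5 ± 1.97 CPM (n = 2 each, edgeR adjusted p = 4.2e-21). Ifit1, whose product binds viral RNA, rose 30.4-fold to 44.1 ± 3.01 CPM, and Isg15 rose 24.5-fold to 7.23 ± 0.752 CPM. Other large rises were those of Sema7a, a membrane-bound semaphorin (50.9-fold), the antiviral GTPase gene Mx2 (38.4-fold), I830012O16Rik (32.8-fold) and Ifit3 (26.1-fold). Among the falls, Rasip1, which encodes a regulator of small GTPases, was at least 6.01-fold lower and Olfr1316 was lower by 9.01-fold (95% counting interval 2.85 to 45.7). Antiviral genes had 48 of 62 members higher and 0 lower, or 48 and 1 adjusted over the list alone, with median log2 change 1.38, camera adjusted p = 1.5e-34 and adjusted p = 0.013 with an estimated correlation. In this list, log2 changes were 2.36 ± 0.055 for Helz2, 2.77 ± 0.091 for Trim21 and 1.57 ± 0.052 for Samd9l. Of the interferon-inducible GTPases, which act against intracellular pathogens, 12 of 17 rose and 0 fell (12 and 0 adjusted over the list alone). The median was 2.53, or 2.25 with members at 0 counts set to their bound, camera adjusted p = 1.1e-12 and adjusted p = 0.040 with an estimated correlation. Irgm1 gave 2.25 ± 0.059, Irgm2 4.37 ± 0.15 and Igtp 3.95 ± 0.16. The list of interferon signalling genes had 13 of 27 members higher and 1 lower, or 13 and 2 adjusted over the list alone. The median was 0.18, camera adjusted p = 3.5e-07 and adjusted p = 0.0094 with an estimated correlation. Its subunits of the transcription factor that drives these genes gave 2.97 ± 0.090 for Irf9 and 2.29 ± 0.076 for Stat2.

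Genes outside the antiviral response also moved in naive WT cells at 2 h. Immediate early genes, which answer growth factors and stress within minutes, had 24 of 27 members higher and 1 lower, or 24 and 1 adjusted over the list alone. The median was 1.28, camera adjusted p = 5.3e-25 and adjusted p = 0.0054 with an estimated correlation. Dusp6 gave 3.55 ± 0.059, Nr4a1 2.45 ± 0.074, Ier3 2.08 ± 0.081 and Egr3 3.71 ± 0.15. Contractile genes and targets of the transcription factor SRF had 21 of 23 members higher and 0 lower, or 22 and 0 adjusted over the list alone. The median was 0.26, camera adjusted p = 3.7e-13 and adjusted p = 0.037 with an estimated correlation. Ctgf gave 2.54 ± 0.048, Cyr61 1.10 ± 0.045 and Srf 1.06 ± 0.049. Chemokines and NF-kB targets had 13 of 24 members higher and 4 lower, or 15 and 4 adjusted over the list alone. The median was 0.66, or 0.52 with members at 0 counts set to their bound, camera adjusted p = 4.2e-05 and adjusted p = 0.020 with an estimated correlation. Ptgs2 gave 2.52 ± 0.048, Cx3cl1 1.41 ± 0.070, Tnfaip3 1.16 ± 0.062 and Lif 1.87 ± 0.11. Of the sensors, log2 changes were 1.68 ± 0.066 for Ddx58 and 2.06 ± 0.21 for Ifih1. Lists of nucleic acid sensors, MHC class I antigen presentation and cholesterol synthesis were also called higher by camera, and of ER stress and ATF4 targets and cell cycle and proliferation lower (adjusted p = 2.2e-05 to 0.016, or adjusted p = 0.081 to 0.56 with an estimated correlation). EdgeR called 4229 of 13802 genes, 2070 higher and 2159 lower, and 261 rose and 194 fell at least 2-fold. Without WT naive 0 h replicate 1 the count was 2737, the cell cycle list had adjusted p = 0.062 without the 3 libraries low in Rn45s, and DESeq2 put 59.6% of its calls higher against 48.9% here. Of the 16 genes that the size rule names here, 9 kept their call whichever library was left out. Without WT naive 0 h replicate 1, 5 lost the call (highest adjusted p = 0.32), and so did 1 without WT naive 0 h replicate 2 (0.084), 7 without WT naive 2 h replicate 1 (0.27) and 5 without WT naive 2 h replicate 2 (0.12).

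In naive KO cells the same treatment raised antiviral genes, measured in a single 2 h library that borrows the spread of the other groups. Ifit1 rose from 3.12 ± 0.681 CPM (n = 2) to 1154 CPM (n = 1), a log2 change of 8.58 ± 0.13 (edgeR adjusted p = 2.7e-29). Mx1, an antiviral GTPase gene, rose 841-fold to 127 CPM, the chemokine gene Cxcl10 529.9-fold to 197 CPM and Rsad2 (viperin) 527-fold to 304 CPM. Serpina3f, a protease inhibitor gene with no count in KO at 0 h, rose at least 193-fold, and the guanylate-binding genes Gbp4 and Gbp11 at least 72.2-fold and at least 68.0-fold. Gm14446 rose 947-fold. Ppp1r3c, a regulatory subunit of a glycogen phosphatase, was at least 6.28-fold lower, and Artn, a neurotrophic factor gene, was lower by 13.0-fold (95% counting interval 2.17 to 527). Antiviral genes had 61 of 62 members higher and 0 lower, or 61 and 0 adjusted over the list alone. The median was 3.96, camera adjusted p = 1.6e-66 and adjusted p = 0.0054 with an estimated correlation. Cmpk2 gave 8.02 ± 0.11, Usp18 7.49 ± 0.10 and Parp14 5.69 ± 0.082. Interferon-inducible GTPases had 17 of 17 members higher and 0 lower, or 17 and 0 adjusted over the list alone. The median was 6.96, or 6.60 with members at 0 counts set to their bound, camera adjusted p = 4.6e-26 and adjusted p = 0.011 with an estimated correlation. Iigp1 gave 8.53 ± 0.11, Gbp2 6.95 ± 0.11 and Igtp 6.96 ± 0.11. MHC class I presentation had 19 of 21 members higher and 0 lower, or 19 and 0 adjusted over the list alone. The median was 1.52, camera adjusted p = 9.6e-18 and adjusted p = 0.012 with an estimated correlation. Tap1 gave 2.76 ± 0.065 and Nlrc5 2.84 ± 0.083. Nucleic acid sensors had 15 of 18 members higher and 2 lower, or 15 and 2 adjusted over the list alone. The median was 2.54, camera adjusted p = 5.5e-13 and adjusted p = 0.015 with an estimated correlation. Ddx58 gave 3.93 ± 0.068, Ifih1 5.52 ± 0.11 and Tlr3 4.32 ± 0.092.

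Chemokines and NF-kB targets in naive KO cells had 21 of 24 members higher and 2 lower, or 21 and 2 adjusted over the list alone. The median was 1.39, camera adjusted p = 1.2e-12 and adjusted p = 0.0054 with an estimated correlation. Ccl2 gave 4.42 ± 0.12. Interferon signalling genes had 15 of 27 members higher and 2 lower, or 15 and 2 adjusted over the list alone. The median was 0.24, camera adjusted p = 1.5e-08 and adjusted p = 0.0076 with an estimated correlation. Irf7 gave 5.53 ± 0.10 and Stat2 3.26 ± 0.069. Immediate early genes had 21 of 27 members higher and 1 lower, or 22 and 1 adjusted over the list alone. The median was 1.0, or 0.95 with members at 0 counts set to their bound, camera adjusted p = 5.2e-14 and adjusted p = 0.0058 with an estimated correlation. Jun gave 1.58 ± 0.064, Junb 1.60 ± 0.065 and Arc 2.37 ± 0.10. Contractile genes and SRF targets had 21 of 23 members higher and 0 lower, or 21 and 0 adjusted over the list alone. The median was 0.58, camera adjusted p = 3.0e-17 and adjusted p = 0.021 with an estimated correlation. Ctgf gave 2.11 ± 0.053, Cyr61 1.77 ± 0.054 and Vcl 1.26 ± 0.050. The list of ER stress and ATF4 targets was also called lower by camera (adjusted p = 0.0043, or adjusted p = 0.23 with an estimated correlation). EdgeR called 5002 of 13802 genes, 2632 higher and 2370 lower, of which 515 rose and 217 fell at least 2-fold. Of the genes called higher in WT, 1243 were also called higher in KO, where independent lists would share 394.7, and of those called lower 1038 were shared against 370.7. The comparisons use different libraries. Of the 16 genes named by size, 13 kept their call whichever other library was left out. The single KO naive 2 h library, on which all of them rest, could not be left out. Without KO naive 0 h replicate 1, 1 lost the call (highest adjusted p = 0.067), and so did 2 without KO naive 0 h replicate 2 (0.34).

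The interferon response differed between KO and WT for many antiviral genes when the difference itself was tested. Ifit1 reached 1154 CPM in KO (n = 1) against 44.1 ± 3.01 CPM in WT (n = 2) at 2 h, and its log2 change was larger in KO by 3.65 ± 0.35 (edgeR adjusted p = 4.3e-09). The differences were 6.41 ± 0.64 for Rsad2, 6.72 ± 0.47 for Cxcl10 and 5.80 ± 0.20 for Gbp2. Gm14446 (8.84 ± 0.90), Misp (7.11 ± 1.10) and Slfn4 (7.0 ± 0.82) also rose more in KO. Of the 16 genes named by size, 5 kept their call whichever library was left out, and 11 lost it in some such fit. Without KO naive 0 h replicate 1, 3 lost the call (highest adjusted p = 0.058), and so did 10 without KO naive 0 h replicate 2 (0.34), 8 without WT naive 0 h replicate 1 (1.0), 5 without WT naive 0 h replicate 2 (0.14), 8 without WT naive 2 h replicate 1 (0.20) and 6 without WT naive 2 h replicate 2 (0.31). Antiviral genes had 53 of 62 members higher and 0 lower, or 56 and 1 adjusted over the list alone. The median was 2.21, camera adjusted p = 5.2e-68 and adjusted p = 0.0054 with an estimated correlation. Ifit2 gave 3.69 ± 0.11, Samd9l 2.37 ± 0.080 and Dtx3l 2.68 ± 0.11. The GTPases had 12 of 17 members higher and 0 lower, or 13 and 0 adjusted over the list alone. The median was 5.06, camera adjusted p = 6.7e-28 and adjusted p = 0.010 with an estimated correlation. MHC class I presentation had 19 of 21 members higher and 0 lower, or 19 and 0 adjusted over the list alone. The median was 1.27, camera adjusted p = 5.3e-21 and adjusted p = 0.0094 with an estimated correlation. Tap1 gave 2.24 ± 0.10, Psmb10 1.88 ± 0.11 and H2-D1 1.27 ± 0.094. Nucleic acid sensors had 12 of 18 members higher and 0 lower, or 14 and 1 adjusted over the list alone. The median was 1.64, camera adjusted p = 6.9e-15 and adjusted p = 0.012 with an estimated correlation. Signalling genes had 12 of 27 members higher and 4 lower, or 12 and 4 adjusted over the list alone. The median was 0.19, camera adjusted p = 0.00016 and adjusted p = 0.022 with an estimated correlation. Irf1 gave 1.73 ± 0.086, Socs1 1.99 ± 0.19 and Stat2 0.97 ± 0.11. Chemokines and NF-kB targets had 15 of 24 members higher and 2 lower, or 17 and 4 adjusted over the list alone. The median was 0.59, camera adjusted p = 2.2e-07 and adjusted p = 0.0094 with an estimated correlation.

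Not every group responded more in KO. Immediate early genes had 5 of 27 members higher and 10 lower, or 8 and 12 adjusted over the list alone in the genotype difference. The median was -0.061, camera adjusted p = 0.014 and adjusted p = 0.13 with an estimated correlation. Dusp6 gave -2.19 ± 0.092, Dusp1 -1.45 ± 0.16 and Nr4a1 -1.49 ± 0.13. Cholesterol synthesis had 0 of 23 members higher and 7 lower, or 0 and 10 adjusted over the list alone. The median was -0.18, camera adjusted p = 3.4e-05 and adjusted p = 0.16 with an estimated correlation. Insig1 gave -0.56 ± 0.076. Contractile genes and SRF targets had 12 of 23 members higher and 2 lower, or 16 and 2 adjusted over the list alone. The median was 0.32, camera adjusted p = 1.2e-06 and adjusted p = 0.12 with an estimated correlation. Cyr61 gave 0.67 ± 0.071, Ankrd1 1.04 ± 0.12 and Acta2 0.66 ± 0.082. EdgeR called 2113 of 13802 genes, 1167 higher and 946 lower, and the 1 KO library at naive 2 h enters each of these values.

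**Figure D2:**
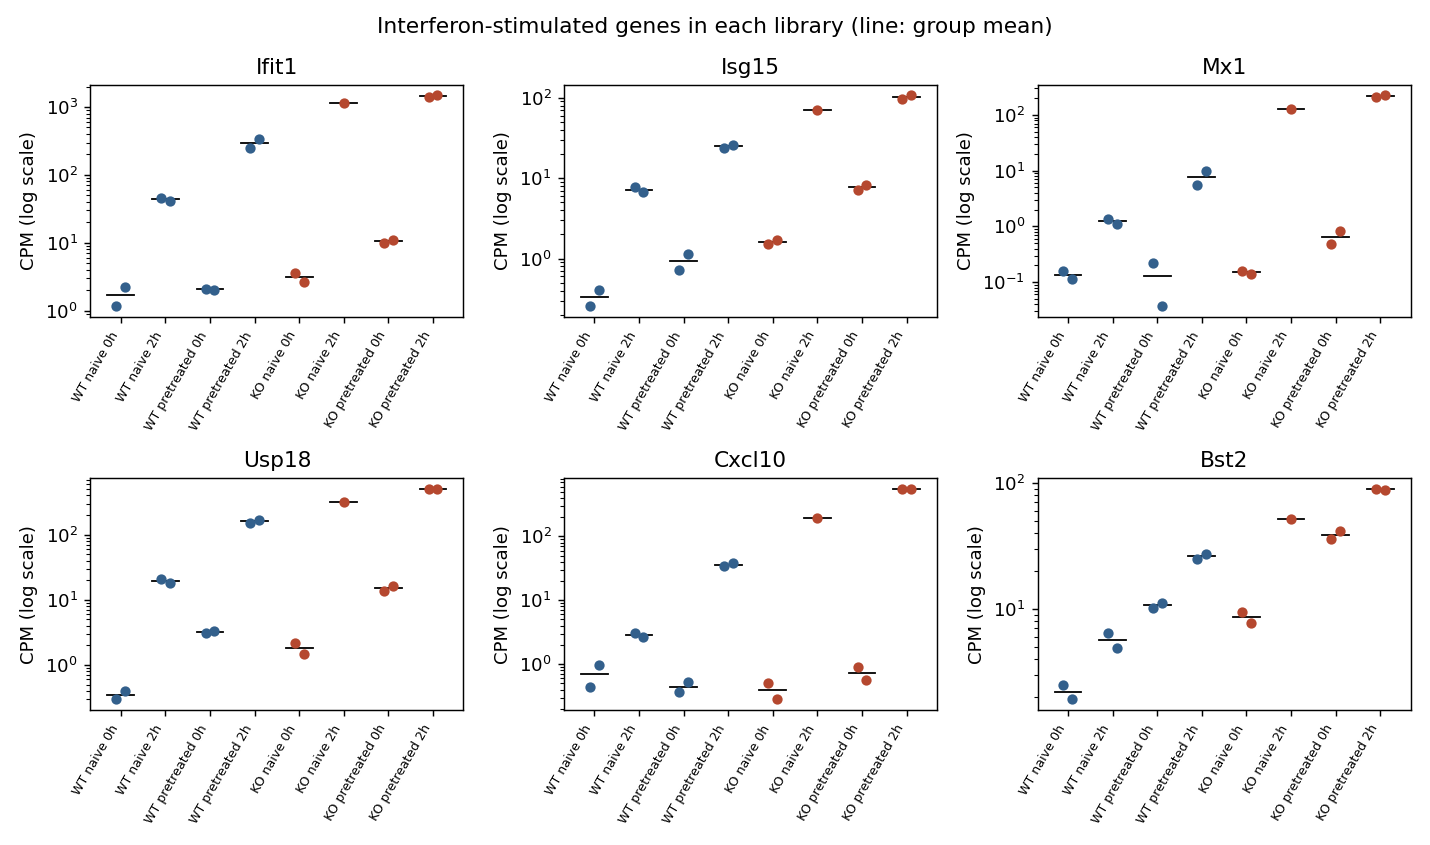
CPM on a log axis of interferon-stimulated genes in the 8 groups; each point is 1 library and the lines give the group means. For Ifit1 the mean was 1154 CPM in the single KO naive 2 h library against 44.1 CPM in WT naive cells at 2 h (n = 2).

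The wash-out comparison set pretreated against naive cells at 0 h, that is 24 h after the end of the first exposure. In WT, Usp18 stood at 3.21 ± 0.216 CPM against 0.350 ± 0.0773 CPM (n = 2 each), 9.80-fold higher (edgeR adjusted p = 7.4e-10). Bst2 (tetherin), which holds virus particles at the cell surface, stood at 10.7 ± 0.661 CPM against 2.19 ± 0.392 CPM, a log2 change of 2.20 ± 0.14, while Ifit1 was at 2.05 ± 0.0814 CPM against 1.71 ± 0.773 CPM (adjusted p = 0.28). Sspo (5.48-fold lower) and Scube3 (5.08-fold lower), both for secreted proteins, were among the falls. Antiviral genes had 30 of 62 members higher and 1 lower, or 35 and 2 adjusted over the list alone. The median was 0.50, camera adjusted p = 4.8e-13 and adjusted p = 0.074 with an estimated correlation. Lgals3bp gave 1.42 ± 0.11 and Ifi27 1.07 ± 0.082. Interferon signalling genes had 9 of 27 members higher and 2 lower, or 9 and 2 adjusted over the list alone, with 1.47 ± 0.10 for Irf9 and 1.62 ± 0.25 for Irf7, and the list was not called (median log2 change 0.036, camera adjusted p = 0.070). Cell cycle genes had 34 of 36 members higher and 0 lower, or 35 and 0 adjusted over the list alone. The median was 0.36, camera adjusted p = 1.6e-29 and adjusted p = 0.021 with an estimated correlation. Mybl2 gave 0.72 ± 0.061, Rrm2 0.55 ± 0.047, Cdc6 0.78 ± 0.067 and Uhrf1 0.46 ± 0.045. Cholesterol synthesis had 21 of 23 members higher and 0 lower, or 22 and 0 adjusted over the list alone. The median was 0.46, camera adjusted p = 1.5e-25 and adjusted p = 0.011 with an estimated correlation. Idi1 gave 1.06 ± 0.047 and Acat2 0.92 ± 0.065. Extracellular matrix genes had 2 of 37 members higher and 17 lower, or 2 and 20 adjusted over the list alone. The median was -0.18, camera adjusted p = 1.8e-09 and adjusted p = 0.043 with an estimated correlation. Fbln5 gave -0.90 ± 0.055, Postn -1.62 ± 0.11, Col3a1 -1.02 ± 0.073 and Lox -0.59 ± 0.047. ER stress and ATF4 targets had 0 of 28 members higher and 21 lower, or 0 and 23 adjusted over the list alone. The median was -0.30, camera adjusted p = 2.9e-13 and adjusted p = 0.020 with an estimated correlation. Ddit4 gave -0.72 ± 0.056, Ddit3 -0.61 ± 0.061 and Trib3 -0.71 ± 0.075.

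In pretreated WT cells at 0 h, the list of immediate early genes was also called higher by camera, and of p53 targets and senescence lower (adjusted p = 0.015 to 0.021, or adjusted p = 0.11 to 0.14 with an estimated correlation). The p53 list had adjusted p = 0.058 without WT naive 0 h replicate 1. EdgeR called 3307 of 13802 genes, 1733 higher and 1574 lower in WT. The count was 2076 without WT naive 0 h replicate 1 and 2172 without the 3 libraries low in Rn45s. In WT, of 16 genes named by size, Usp18, Sspo and Scube3 kept their call whichever library was left out, and 13 did not. Without WT naive 0 h replicate 1, 11 lost the call (highest adjusted p = 0.43), and so did 6 without WT naive 0 h replicate 2 (0.13), 8 without WT pretreated 0 h replicate 1 (0.31) and 8 without WT pretreated 0 h replicate 2 (0.42).

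Pretreated KO cells at 0 h held more antiviral transcripts than naive KO cells. Bst2 stood at 38.7 ± 3.86 CPM against 8.63 ± 1.19 CPM (n = 2 each), a log2 change of 2.19 ± 0.092 (edgeR adjusted p = 2.7e-16), Usp18 at 15.1 ± 1.86 CPM against 1.81 ± 0.515 CPM, and Ifit1 at 10.5 ± 0.788 CPM against 3.12 ± 0.681 CPM (1.80 ± 0.18). Genes of the oligoadenylate synthetases, which sense double-stranded RNA, were higher, Oas1a 16.9-fold, Oas2 16.4-fold and Oas1g at least 10.4-fold, as was Apol9b (15.8-fold). Lum (lumican), a collagen-binding proteoglycan (5.08-fold), and Trp63, a transcription factor of epithelia (6.64-fold), were lower. Antiviral genes had 54 of 62 members higher and 1 lower, or 56 and 1 adjusted over the list alone. The median was 1.06, camera adjusted p = 1.6e-47 and adjusted p = 0.0094 with an estimated correlation. Lgals3bp gave 1.49 ± 0.076 and Xaf1 2.5 ± 0.13. The GTPases had 13 of 17 members higher and 0 lower, or 14 and 0 adjusted over the list alone. The median was 1.97, or 1.48 with members at 0 counts set to their bound, camera adjusted p = 4.7e-14 and adjusted p = 0.037 with an estimated correlation. Iigp1 gave 2.81 ± 0.18, Irgm1 0.86 ± 0.057 and Gbp3 3.05 ± 0.22. Cell cycle genes had 30 of 36 members higher and 0 lower, or 31 and 0 adjusted over the list alone. The median was 0.23, camera adjusted p = 1.1e-19 and adjusted p = 0.043 with an estimated correlation. Rrm2 gave 0.42 ± 0.046, Ccne2 0.74 ± 0.084 and Pcna 0.35 ± 0.045. ER stress and ATF4 targets had 0 of 28 members higher and 18 lower, or 0 and 18 adjusted over the list alone. The median was -0.17, camera adjusted p = 3.0e-08 and adjusted p = 0.045 with an estimated correlation. Ddit4 gave -0.76 ± 0.065 and Trib3 -0.66 ± 0.072. Cholesterol synthesis was not called (2 of 23 members higher and 6 lower, or 2 and 7 adjusted over the list alone; median log2 change -0.060, camera adjusted p = 0.26).

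In pretreated KO cells at 0 h, Dcn (decorin), a matrix proteoglycan gene, gave -1.86 ± 0.21, and of the MHC class I genes 0.84 ± 0.058 for H2-D1 and 0.66 ± 0.046 for B2m. Lists of MHC class I antigen presentation, nucleic acid sensors, contractile and SRF targets and immediate early genes were also called higher by camera, and of fibroblast extracellular matrix lower (adjusted p = 4.3e-10 to 0.0074, or adjusted p = 0.057 to 0.15 with an estimated correlation). The immediate early genes had adjusted p = 0.051 without KO pretreated 0 h replicate 1. EdgeR called 2995 of 13802 genes, 1533 higher and 1462 lower in KO, falling to 1897 without KO naive 0 h replicate 2 and 1956 without KO pretreated 0 h replicate 2. Of those called higher in WT, 937 were also called higher in KO against 192.5 for independent lists, and of those lower 670 against 166.7. Of 16 named by size in KO at 0 h, 9 kept their call in every leave-one-out fit. Without KO naive 0 h replicate 1, 4 lost the call (highest adjusted p = 0.084), and so did 5 without KO naive 0 h replicate 2 (0.18), 3 without KO pretreated 0 h replicate 1 (0.31) and 4 without KO pretreated 0 h replicate 2 (0.44).

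When the wash-out effect was compared between genotypes, most cholesterol genes and some antiviral genes passed the test of the difference. Ifi44 (2.97 ± 0.46), Gbp9 (2.89 ± 0.59), Iigp1 (2.54 ± 0.49) and Ifih1 (1.71 ± 0.31) were raised more in KO, and the cytokine gene Il33 (-2.10 ± 0.25), Dcn (-1.91 ± 0.24) and the chemokine gene Ccl9 (-1.79 ± 0.14) changed in the lower direction relative to WT (edgeR adjusted p from 4.0e-09 for Ccl9 to 0.0033 for Gbp9). Antiviral genes had 15 of 62 members higher and 0 lower, or 24 and 0 adjusted over the list alone. The median was 0.60, camera adjusted p = 1.4e-22 and adjusted p = 0.031 with an estimated correlation. The GTPases had 6 of 17 members higher and 0 lower, or 7 and 0 adjusted over the list alone. The median was 1.5, camera adjusted p = 9.0e-14 and adjusted p = 0.037 with an estimated correlation. Cholesterol synthesis had 0 of 23 members higher and 21 lower, or 0 and 22 adjusted over the list alone. The median was -0.55, camera adjusted p = 2.2e-47 and adjusted p = 0.0054 with an estimated correlation. Idi1 gave -0.86 ± 0.064, Insig1 -0.74 ± 0.068, Nsdhl -0.73 ± 0.076 and Fdps -0.59 ± 0.063. Cartilage and bone markers had 1 of 12 members higher and 2 lower, or 1 and 3 adjusted over the list alone. The median was -0.23, camera adjusted p = 0.0018 and adjusted p = 0.042 with an estimated correlation. Mgp gave -1.18 ± 0.10 and Spp1 -0.56 ± 0.092. Lists of MHC class I antigen presentation, nucleic acid sensors, fibroblast extracellular matrix, contractile and SRF targets and ER stress and ATF4 targets were also called higher by camera, and of cell cycle and proliferation lower (adjusted p = 5.1e-10 to 0.0016, or adjusted p = 0.057 to 0.19 with an estimated correlation). The matrix list had a positive median (0.15) and a negative mean (-0.086), and ER stress had adjusted p = 0.055 without KO pretreated 0 h replicate 2 and 0.084 without the 3 libraries low in Rn45s. EdgeR called 445 of 13802 genes, 236 higher and 209 lower, and the count was 262 without KO naive 0 h replicate 2, 274 without KO pretreated 0 h replicate 2, 281 without WT naive 0 h replicate 1 and 219 without the 3 libraries low in Rn45s.

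Restimulation of pretreated WT cells for 2 h raised the antiviral genes again. Ifit1 rose 142-fold from 2.05 ± 0.0814 CPM to 293 ± 58.2 CPM (n = 2 each, edgeR adjusted p = 6.2e-26) and Ifit3 82.6-fold. Zbp1, a sensor of Z-form nucleic acid, rose at least 20.6-fold, Oasl1 at least 13.3-fold and the transcription factor gene Batf2 at least 9.07-fold, each from no count, and I830012O16Rik rose 121-fold. Bmf, a pro-apoptotic member of the BCL2 family, fell 6.96-fold. Antiviral genes had 58 of 62 members higher and 0 lower, or 59 and 0 adjusted over the list alone. The median was 2.62, camera adjusted p = 1.9e-74 and adjusted p = 0.0054 with an estimated correlation. Usp18 gave 5.63 ± 0.093, Helz2 3.09 ± 0.053 and Trim21 4.43 ± 0.078. The GTPases had 14 of 17 members higher and 0 lower, or 15 and 0 adjusted over the list alone. The median was 4.50, or 4.11 with members at 0 counts set to their bound, camera adjusted p = 1.2e-24 and adjusted p = 0.012 with an estimated correlation. Irgm1 gave 2.88 ± 0.057, Irgm2 4.97 ± 0.11 and Igtp 4.95 ± 0.11. MHC class I presentation had 15 of 21 members higher and 0 lower, or 15 and 0 adjusted over the list alone. The median was 0.59, camera adjusted p = 1.0e-12 and adjusted p = 0.021 with an estimated correlation. Tap1 gave 1.86 ± 0.068, Tapbp 0.81 ± 0.051 and Psmb10 1.17 ± 0.076. Nucleic acid sensors had 12 of 18 members higher and 2 lower, or 12 and 3 adjusted over the list alone. The median was 1.25, camera adjusted p = 8.2e-12 and adjusted p = 0.020 with an estimated correlation. Ddx58 gave 2.18 ± 0.061 and Tlr3 2.65 ± 0.077. Interferon signalling genes had 13 of 27 members higher and 1 lower, or 15 and 4 adjusted over the list alone. The median was 0.19, camera adjusted p = 5.7e-08 and adjusted p = 0.0086 with an estimated correlation. Irf7 gave 4.60 ± 0.11.

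Outside these groups, pretreated WT cells raised immediate early genes (21 of 27 members higher and 1 lower, or 21 and 1 adjusted over the list alone; median log2 change 0.74, camera adjusted p = 1.0e-21 and adjusted p = 0.0054 with an estimated correlation). Dusp6 gave 2.85 ± 0.057, Junb 1.29 ± 0.055 and Egr3 3.22 ± 0.17. They also raised contractile genes (20 of 23 members higher and 0 lower, or 20 and 0 adjusted over the list alone; median log2 change 0.22, camera adjusted p = 2.6e-12 and adjusted p = 0.040 with an estimated correlation). Ctgf gave 1.81 ± 0.047 and Ankrd1 1.10 ± 0.049. They raised chemokines too (14 of 24 members higher and 3 lower, or 16 and 3 adjusted over the list alone; median log2 change 0.69, camera adjusted p = 8.1e-09 and adjusted p = 0.0076 with an estimated correlation). Cxcl10 gave 6.34 ± 0.16. The list of ER stress and ATF4 targets was also called lower by camera (adjusted p = 0.0047, or adjusted p = 0.23 with an estimated correlation). Cartilage and bone markers (3 of 12 members higher and 1 lower, or 3 and 2 adjusted over the list alone; median log2 change 0.21, or 0.12 with members at 0 counts set to their bound, camera adjusted p = 0.047 and adjusted p = 0.14 with an estimated correlation) lost their call in 7 of the 15 leave-one-out fits, the highest adjusted p being 0.093 without WT pretreated 0 h replicate 2, and also with RLE factors (0.058), no filter (0.11) and Rn45s and Lars2 out of the counts (0.080). EdgeR called 3138 of 13802 genes, 1682 higher and 1456 lower. The calls were 53.6% higher here, 63.9% with DESeq2, 63.9% with Rn45s and Lars2 out of the counts and 67.1% without WT pretreated 0 h replicate 1. Of the 16 genes named by size, 9 kept their call whichever library was left out. Without WT pretreated 0 h replicate 1, 5 lost the call (highest adjusted p = 0.31), and so did 3 without WT pretreated 0 h replicate 2 (0.12), 4 without WT pretreated 2 h replicate 1 (0.19) and 6 without WT pretreated 2 h replicate 2 (0.18).

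Restimulation of pretreated KO cells raised antiviral and chemokine genes. Rsad2 rose 533-fold from 1.57 ± 0.104 CPM to 841 ± 22.8 CPM (n = 2 each, edgeR adjusted p = 6.6e-34), Cxcl10 740.0-fold to 552 ± 5.35 CPM and Mx1 339-fold to 218 ± 8.23 CPM. Gm14446 rose 668-fold, Gm12250 281-fold, Sectm1a at least 50.7-fold and Epsti1 at least 22.2-fold, the last pair from no count. Pde4b, a cyclic AMP phosphodiesterase gene, fell 5.54-fold and Pgf, a growth factor gene of the VEGF family, 4.80-fold. Antiviral genes had 61 of 62 members higher and 0 lower, or 61 and 0 adjusted over the list alone. The median was 3.21, camera adjusted p = 6.3e-67 and adjusted p = 0.0054 with an estimated correlation. Cmpk2 gave 6.44 ± 0.069, Usp18 5.05 ± 0.069 and Parp14 4.63 ± 0.065. The GTPases had 17 of 17 members higher and 0 lower, or 17 and 0 adjusted over the list alone. The median was 5.41, or 5.40 with members at 0 counts set to their bound, camera adjusted p = 1.5e-26 and adjusted p = 0.011 with an estimated correlation. Iigp1 gave 6.39 ± 0.080, Gbp2 6.47 ± 0.086 and Igtp 5.37 ± 0.078. MHC class I presentation had 20 of 21 members higher and 0 lower, or 20 and 0 adjusted over the list alone. The median was 1.61, camera adjusted p = 6.7e-21 and adjusted p = 0.0094 with an estimated correlation. Tap1 gave 2.93 ± 0.056 and Nlrc5 2.92 ± 0.063. Nucleic acid sensors had 15 of 18 members higher and 2 lower, or 16 and 2 adjusted over the list alone. The median was 2.45, camera adjusted p = 5.2e-14 and adjusted p = 0.013 with an estimated correlation. Tlr3 gave 4.88 ± 0.076 and Ifih1 4.35 ± 0.074. Signalling genes had 15 of 27 members higher and 2 lower, or 17 and 2 adjusted over the list alone. The median was 0.24, camera adjusted p = 3.3e-10 and adjusted p = 0.0054 with an estimated correlation. Irf1 gave 2.94 ± 0.053 and Irf7 3.89 ± 0.071. Chemokines had 20 of 24 members higher and 2 lower, or 20 and 2 adjusted over the list alone. The median was 1.31, camera adjusted p = 4.0e-13 and adjusted p = 0.0054 with an estimated correlation. Ccl2 gave 3.70 ± 0.10 and Csf1 1.32 ± 0.047.

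Immediate early genes in restimulated KO cells had 23 of 27 members higher and 0 lower, or 23 and 0 adjusted over the list alone. The median was 0.99, or 0.95 with members at 0 counts set to their bound, camera adjusted p = 4.6e-16 and adjusted p = 0.0054 with an estimated correlation. Junb gave 1.79 ± 0.054, Jun 1.51 ± 0.051 and Arc 2.07 ± 0.080. Contractile genes had 22 of 23 members higher and 0 lower, or 23 and 0 adjusted over the list alone. The median was 0.43, camera adjusted p = 3.8e-18 and adjusted p = 0.020 with an estimated correlation. Ctgf gave 2.67 ± 0.048 and Cyr61 1.60 ± 0.045. Of the matrix genes, log2 changes were 2.72 ± 0.048 for Thbs1 and 1.25 ± 0.047 for Tnc. The list of fibroblast extracellular matrix was also called higher by camera, and of ER stress and ATF4 targets and cholesterol synthesis lower (adjusted p = 0.0042 to 0.042, or adjusted p = 0.23 to 0.46 with an estimated correlation). Cholesterol synthesis lost its call without KO pretreated 0 h replicate 2 (adjusted p = 0.080) and without KO pretreated 2 h replicate 2 (0.11). EdgeR called 4346 of 13802 genes, 2475 higher and 1871 lower. Shared with WT were 1213 genes called higher, against 301.6 for independent lists, and 829 called lower, against 197.4. Of 16 genes named by size, 12 kept their call whichever library was left out. Without KO pretreated 0 h replicate 1, 3 lost the call (highest adjusted p = 0.10), and so did 1 without KO pretreated 0 h replicate 2 (0.16), 3 without KO pretreated 2 h replicate 1 (0.18) and 2 without KO pretreated 2 h replicate 2 (0.094).

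At 2 h, pretreated WT cells held more antiviral transcripts than naive WT cells. Ifit1 stood at 293 ± 58.2 CPM against 44.1 ± 3.01 CPM (n = 2 each), a log2 change of 2.73 ± 0.091 (edgeR adjusted p = 1.6e-19), and Usp18 at 159 ± 9.38 CPM against 19.5 ± 1.97 CPM (3.01 ± 0.070). Cxcl10 was 12.3-fold higher, Oas2 11.9-fold and Ccrl2, an atypical chemokine receptor gene with no count in naive WT cells, at least 5.88-fold. Scara5, a ferritin receptor gene (6.30-fold), and the matrix proteoglycan genes Fmod (12.4-fold) and Prelp (5.77-fold) were lower. Antiviral genes had 57 of 62 members higher and 0 lower, or 60 and 0 adjusted over the list alone. The median was 1.69, camera adjusted p = 2.4e-57 and adjusted p = 0.0071 with an estimated correlation. Trim21 gave 1.88 ± 0.059 and Dtx3l 1.69 ± 0.059. The GTPases had 13 of 17 members higher and 0 lower, or 15 and 0 adjusted over the list alone. The median was 2.03, or 1.77 with members at 0 counts set to their bound, camera adjusted p = 2.0e-14 and adjusted p = 0.035 with an estimated correlation. Igtp gave 1.95 ± 0.078, Irgm2 1.77 ± 0.077 and Gbp2 2.03 ± 0.091. Nucleic acid sensors had 10 of 18 members higher and 1 lower, or 12 and 2 adjusted over the list alone. The median was 0.78, camera adjusted p = 7.1e-08 and adjusted p = 0.040 with an estimated correlation. Tlr3 gave 1.82 ± 0.071 and Ifih1 2.39 ± 0.11. Of the presentation and signalling genes, log2 changes were 1.16 ± 0.063 for Tap1, 0.51 ± 0.047 for B2m and 1.99 ± 0.078 for Irf7.

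As at 0 h, cell cycle genes were higher in pretreated WT cells at 2 h (35 of 36 members higher and 0 lower, or 36 and 0 adjusted over the list alone; median log2 change 0.42, camera adjusted p = 3.3e-31 and adjusted p = 0.020 with an estimated correlation). Mcm3 gave 0.59 ± 0.043, Cdc6 0.91 ± 0.071 and Mybl2 0.79 ± 0.063. Cholesterol genes were higher too (15 of 23 members higher and 0 lower, or 17 and 0 adjusted over the list alone; median log2 change 0.33, camera adjusted p = 5.7e-12 and adjusted p = 0.040 with an estimated correlation). Idi1 gave 0.85 ± 0.047 and Lss 0.68 ± 0.054. Extracellular matrix genes were lower (1 of 37 members higher and 21 lower, or 1 and 21 adjusted over the list alone; median log2 change -0.25, or -0.21 with members at 0 counts set to their bound, camera adjusted p = 1.5e-10 and adjusted p = 0.038 with an estimated correlation). Fbln5 gave -0.91 ± 0.057, Col5a1 -0.62 ± 0.044 and Col6a1 -0.86 ± 0.062. ER stress and ATF4 targets were lower too (0 of 28 members higher and 16 lower, or 0 and 17 adjusted over the list alone; median log2 change -0.22, camera adjusted p = 8.2e-09 and adjusted p = 0.040 with an estimated correlation). Xbp1 gave -0.57 ± 0.054 and Atf3 -1.11 ± 0.11. Lists of MHC class I antigen presentation and interferon signalling and its regulators were also called higher by camera, and of p53 targets and senescence and immediate early genes lower (adjusted p = 2.5e-07 to 0.025, or adjusted p = 0.059 to 0.15 with an estimated correlation). The immediate early genes had adjusted p = 0.066 without WT pretreated 2 h replicate 1 and 0.062 without the 3 libraries low in Rn45s. EdgeR called 3447 of 13802 genes, 1822 higher and 1625 lower, or 2278 genes without WT naive 2 h replicate 1. At 2 h in WT, of 16 genes named by size, 7 kept their call whichever library was left out. Without WT naive 2 h replicate 1, 7 lost the call (highest adjusted p = 0.35), and so did 5 without WT naive 2 h replicate 2 (0.14), 5 without WT pretreated 2 h replicate 1 (0.24) and 6 without WT pretreated 2 h replicate 2 (0.41).

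Pretreated KO cells at 2 h were compared with the single naive KO library at 2 h. Ifit1 stood at 1434 ± 66.8 CPM (n = 2) against 1154 CPM (n = 1), and Rsad2 at 841 ± 22.8 CPM against 304 CPM, a log2 change of 1.47 ± 0.064 (edgeR adjusted p = 9.8e-16). Pax5, a B-cell transcription factor gene with no count in the naive library, was at least 4.53-fold higher, and P2rx7, an ATP-gated channel gene, 5.52-fold. Kng1 was 9.04-fold lower, and Ica1 and Zic1 were at or under the floor of 3 counts on both sides, so no fold is given. Antiviral genes had 50 of 62 members higher and 0 lower, or 54 and 0 adjusted over the list alone. The median was 0.46, camera adjusted p = 1.1e-14 and adjusted p = 0.059 with an estimated correlation. Cmpk2 gave 1.23 ± 0.059, Oas2 1.78 ± 0.12 and Daxx 0.62 ± 0.053. The GTPases had 10 of 17 members higher and 0 lower, or 12 and 0 adjusted over the list alone, with 0.67 ± 0.069 for Iigp1 and 0.60 ± 0.070 for Gbp2, and were not called (median log2 change 0.32, camera adjusted p = 0.054). Other log2 changes were 1.01 ± 0.070 for Nlrc5 and 0.54 ± 0.064 for H2-D1 among MHC class I genes, 0.71 ± 0.079 for Mybl2 and 0.43 ± 0.056 for Uhrf1 in the cell cycle list and Insig1 at -0.73 ± 0.056 in the cholesterol list. Lists of MHC class I antigen presentation, cell cycle and proliferation and contractile and SRF targets were also called higher by camera, and of cholesterol synthesis and ER stress and ATF4 targets lower (adjusted p = 2.5e-12 to 0.00099, or adjusted p = 0.10 to 0.25 with an estimated correlation). The ER stress list had a negative median (-0.14) and a positive mean (0.087). EdgeR called 2598 of 13802 genes, 1548 higher and 1050 lower, or 1674 genes without KO pretreated 2 h replicate 1 and 1646 when only the compared groups entered the fit. Among the 16 genes named by size, 7 kept their call whichever library was left out. Without KO pretreated 2 h replicate 1, 9 lost the call (highest adjusted p = 0.48), and so did 4 without KO pretreated 2 h replicate 2 (0.13). Of all called genes, 717 of the genes called higher were shared with WT, against 204.4 for independent lists, and 450 of those called lower, against 123.6.

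The effect of pretreatment at 2 h was smaller in KO than in WT for most antiviral genes when the difference was tested. The log2 differences were -2.41 ± 0.13 for Ifit1, -2.33 ± 0.095 for Usp18, -2.39 ± 0.12 for Ifi203 and -1.34 ± 0.084 for Trim21 (edgeR adjusted p = 4.5e-14 for Ifit1), and further ones -3.17 ± 0.30 for Gm14446 and -3.79 ± 0.74 for Sorl1. Antiviral genes had 0 of 62 members higher and 51 lower, or 0 and 54 adjusted over the list alone. The median was -1.24, camera adjusted p = 2.2e-44 and adjusted p = 0.0094 with an estimated correlation. The GTPases had 0 of 17 members higher and 12 lower, or 0 and 12 adjusted over the list alone. The median was -1.5, camera adjusted p = 4.9e-13 and adjusted p = 0.040 with an estimated correlation. Mx2 gave -2.13 ± 0.14, Gbp7 -2.20 ± 0.15 and Igtp -1.54 ± 0.10. Nucleic acid sensors had 0 of 18 members higher and 8 lower, or 1 and 8 adjusted over the list alone. The median was -0.56, camera adjusted p = 4.4e-07 and adjusted p = 0.047 with an estimated correlation. Interferon signalling genes had 0 of 27 members higher and 6 lower, or 0 and 7 adjusted over the list alone. The median was -0.053, camera adjusted p = 0.0011 and adjusted p = 0.037 with an estimated correlation. Irf7 gave -1.47 ± 0.10. Cholesterol synthesis had 0 of 23 members higher and 17 lower, or 0 and 17 adjusted over the list alone. The median was -0.50, camera adjusted p = 1.5e-22 and adjusted p = 0.013 with an estimated correlation. Idi1 gave -1.02 ± 0.070 and Insig1 -0.85 ± 0.075. In the other direction, extracellular matrix genes had 19 of 37 members higher and 1 lower, or 20 and 1 adjusted over the list alone. The median was 0.32, camera adjusted p = 1.0e-10 and adjusted p = 0.037 with an estimated correlation. Col5a1 gave 0.82 ± 0.071, Col1a1 1.28 ± 0.12 and Col3a1 0.98 ± 0.11. Immediate early genes had 10 of 27 members higher and 0 lower, or 11 and 0 adjusted over the list alone. The median was 0.28, camera adjusted p = 2.9e-05 and adjusted p = 0.035 with an estimated correlation. Atf3 gave 1.54 ± 0.17 and Fosl2 0.53 ± 0.084. The list of contractile and SRF targets was also called higher by camera, and of MHC class I antigen presentation and cell cycle and proliferation lower (adjusted p = 5.4e-12 to 0.031, or adjusted p = 0.10 to 0.36 with an estimated correlation). MHC class I presentation lost its call without KO pretreated 2 h replicate 2 (adjusted p = 0.050), WT naive 2 h replicate 2 (0.16) and WT pretreated 2 h replicate 2 (0.10). EdgeR called 1248 of 13802 genes, 704 higher and 544 lower, or 778 genes without WT naive 2 h replicate 1 and 814 without KO pretreated 2 h replicate 1. The lone KO naive 2 h library enters every value here.

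**Figure D3:**
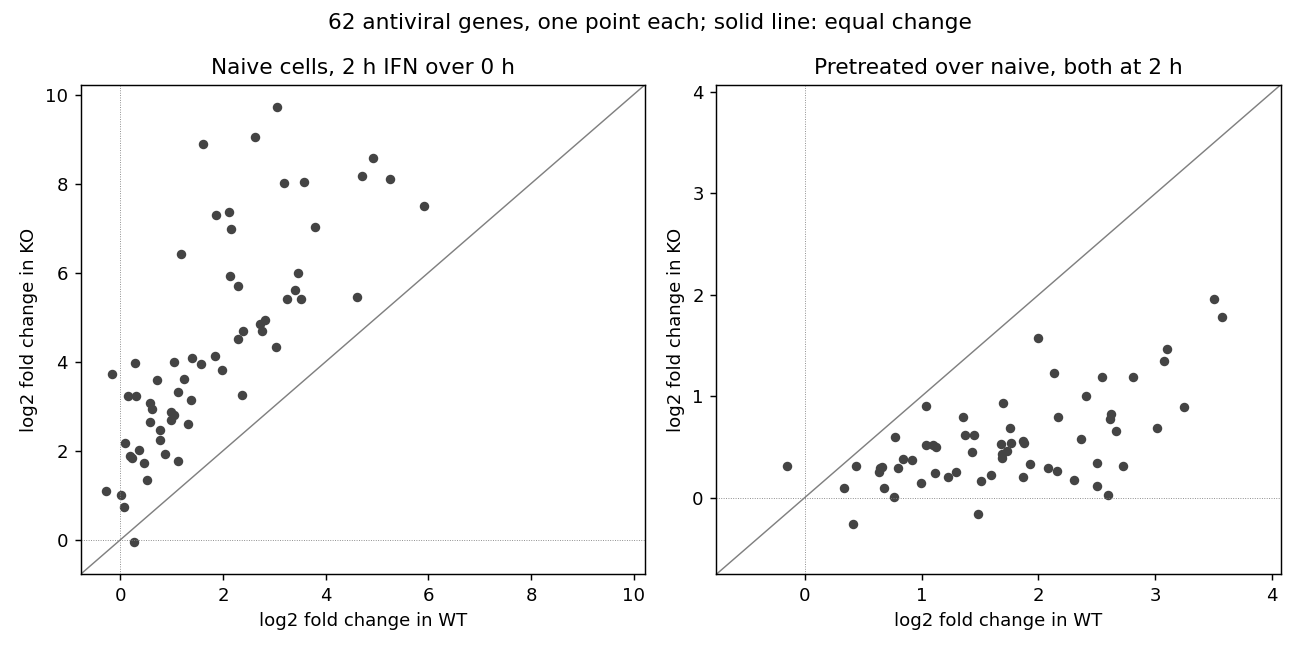
Log2 fold change in KO (vertical axis) against that in WT (horizontal axis) for 62 antiviral genes, 1 point each, for 2 h of interferon over 0 h in naive cells (left) and for pretreated over naive cells at 2 h (right); the solid line marks equal change. The median of the difference was 2.21 on the left and -1.24 on the right, and the KO side has 1 naive library at 2 h. That library enters both panels with opposite signs.

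KO and WT libraries differed at most genes tested. Averaged over the 4 conditions, Cdca7l, a MYC-interacting gene, was 956-fold higher in KO (edgeR adjusted p = 1.9e-28), Uchl1, a deubiquitinase gene, at least 346-fold and the endothelin receptor gene Ednra at least 238-fold. Cyba, a subunit of NADPH oxidase, was higher by 2051-fold (95% counting interval 368 to 81062) and Serpine2 by 613-fold (95% counting interval 209.6 to 2977). Hoxd8 (1472-fold) and Hoxd9 (489-fold), which encode patterning factors of the trunk and limb, and H2-M1 (469-fold) were lower, as was the cardiac factor gene Nkx2-5 by 545-fold (95% counting interval 186 to 2643). Of the Hox genes 7 of 25 were higher and 15 lower (7 and 15 adjusted over the list alone), and the list was not called (median log2 change -0.53, camera adjusted p = 0.14). Mesenchymal patterning factors split 20 higher to 13 lower of 36 (the same adjusted over the list alone). The list was not called (median log2 change 0.46, camera adjusted p = 0.34). Tbx20 gave 4.03 ± 0.052 and Gata6 3.43 ± 0.068. Interferon signalling genes had 24 of 27 members higher and 1 lower, or 24 and 1 adjusted over the list alone. The median was 0.79, camera adjusted p = 5.6e-07 and adjusted p = 0.0095 with an estimated correlation. Irf5 gave 1.56 ± 0.034 and Irf9 1.44 ± 0.038. Chemokines and NF-kB targets had 18 of 24 members higher and 3 lower, or 18 and 3 adjusted over the list alone. The median was 0.86, camera adjusted p = 0.00050 and adjusted p = 0.035 with an estimated correlation. Vcam1 gave 6.04 ± 0.042, Il1rn 4.58 ± 0.038 and Cx3cl1 2.42 ± 0.031. Lists of antiviral ISGs, interferon-inducible GTPases, MHC class I antigen presentation, nucleic acid sensors, cholesterol synthesis and imprinted genes were also called higher by camera, and of contractile and SRF targets, ER stress and ATF4 targets and p53 targets and senescence lower (adjusted p = 1.3e-15 to 0.044, or adjusted p = 0.055 to 0.33 with an estimated correlation). EdgeR called 10964 of 13802 genes, 5698 higher and 5266 lower, and 1668 were higher and 1057 lower at least 2-fold. The single KO naive 2 h library is part of this mean.

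Before any interferon, naive KO and WT cells already stood apart. Gda (guanine deaminase), Matn4 (a matrilin) and Serpine2 had no count in WT at 0 h and were at least 306-fold, at least 294-fold and at least 293-fold higher in KO (n = 2 each, edgeR adjusted p = 8.1e-19 for Gda). Pdlim3, a muscle cytoskeletal gene, H2-M1 and Lincrna-cox2 had none in KO and were at least 111-fold, at least 72.0-fold and at least 70.0-fold lower. Some antiviral genes were higher in KO, with 3.39 ± 0.13 for Parp12, 4.12 ± 0.17 for Ifi203 and 2.47 ± 0.12 for Ube2l6, and others lower, and the list had 39 of 62 members higher and 8 lower, or 40 and 10 adjusted over the list alone. The median was 0.86, camera adjusted p = 6.1e-05 and adjusted p = 0.27 with an estimated correlation. Cholesterol synthesis had 22 of 23 members higher and 0 lower, or 22 and 0 adjusted over the list alone. The median was 1.09, camera adjusted p = 4.2e-13 and adjusted p = 0.037 with an estimated correlation. Fdps gave 1.34 ± 0.045 and Insig1 1.39 ± 0.049. Interferon signalling genes had 20 of 27 members higher and 1 lower, or 20 and 1 adjusted over the list alone. The median was 0.48, camera adjusted p = 1.9e-05 and adjusted p = 0.015 with an estimated correlation. Socs3 gave 2.00 ± 0.085, Irf9 1.98 ± 0.10 and Tyk2 1.13 ± 0.066. Other log2 changes were -4.18 ± 0.072 for Ankrd1 and -6.05 ± 0.11 for Actg2 among contractile genes, 5.40 ± 0.15 for H2-K1 and 3.34 ± 0.15 for Nlrc5 among MHC class I genes, -4.91 ± 0.067 for Perp and -3.94 ± 0.092 for Cdkn2a in the p53 list and 9.46 ± 0.10 for Rian and 9.15 ± 0.11 for Meg3, both maternally expressed imprinted RNAs. Lists of MHC class I antigen presentation, imprinted genes, cell cycle and proliferation, chemokines and NF-kB targets and cartilage and bone markers were also called higher by camera, and of contractile and SRF targets, p53 targets and senescence and ER stress and ATF4 targets lower (adjusted p = 2.5e-09 to 0.037, or adjusted p = 0.056 to 0.60 with an estimated correlation). The chemokine list had adjusted p = 0.069 with no filter on low counts. EdgeR called 9258 of 13802 genes, 4738 higher and 4520 lower.

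Markers of other cell types also differed between the genotypes without a called direction for most lists. At naive 0 h, cartilage and bone markers had 8 of 12 members higher and 2 lower, or 9 and 2 adjusted over the list alone. The median was 1.20, camera adjusted p = 0.037 and adjusted p = 0.12 with an estimated correlation. Col2a1 gave 6.76 ± 0.092 and Spp1 4.38 ± 0.072. Neural and glial markers had 5 of 10 members higher and 5 lower, or 5 and 5 adjusted over the list alone. The median was 0.49, camera adjusted p = 0.78. Nes gave 7.10 ± 0.10 and Ncam1 -1.76 ± 0.054. Endothelial markers had 6 of 10 members higher and 3 lower, or 6 and 3 adjusted over the list alone. The median was 1.81, camera adjusted p = 0.19. Flt1 gave 3.58 ± 0.19 and Eng 1.51 ± 0.14. Epithelial markers had 3 of 6 members higher and 1 lower, or 3 and 1 adjusted over the list alone. The median was 0.96, camera adjusted p = 0.27. Krt19 gave 1.65 ± 0.070 and Krt8 -1.45 ± 0.35. Skeletal muscle markers had 4 of 9 members higher and 2 lower, or 4 and 2 adjusted over the list alone. The median was 0.57, camera adjusted p = 0.94. Tnnt2 gave -5.18 ± 0.15 and Acta1 2.00 ± 0.25. Adipocyte markers had 5 of 9 members higher and 2 lower, or 5 and 2 adjusted over the list alone. The median was 0.85, camera adjusted p = 0.29. Scd1 gave 1.20 ± 0.042 and Cebpa 7.40 ± 0.27. Macrophage and blood markers had 2 of 7 members higher and 3 lower, or 2 and 3 adjusted over the list alone. The median was -0.028, camera adjusted p = 0.68. Csf1r gave -2.54 ± 0.37 and Cd14 -0.62 ± 0.10. Extracellular matrix genes, which MEFs themselves express, had 19 of 37 members higher and 13 lower, or 19 and 13 adjusted over the list alone. The median was 0.27, camera adjusted p = 0.46. Loxl2 gave 4.21 ± 0.070, Pdgfra 4.27 ± 0.071 and Thbs1 -2.17 ± 0.047. Of the sex-linked genes, Xist reached at most 0.237 CPM in any library, and Ddx3y, a Y-linked helicase gene, averaged 29.3 CPM in WT and 70.7 CPM in KO.

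**Figure D4:**
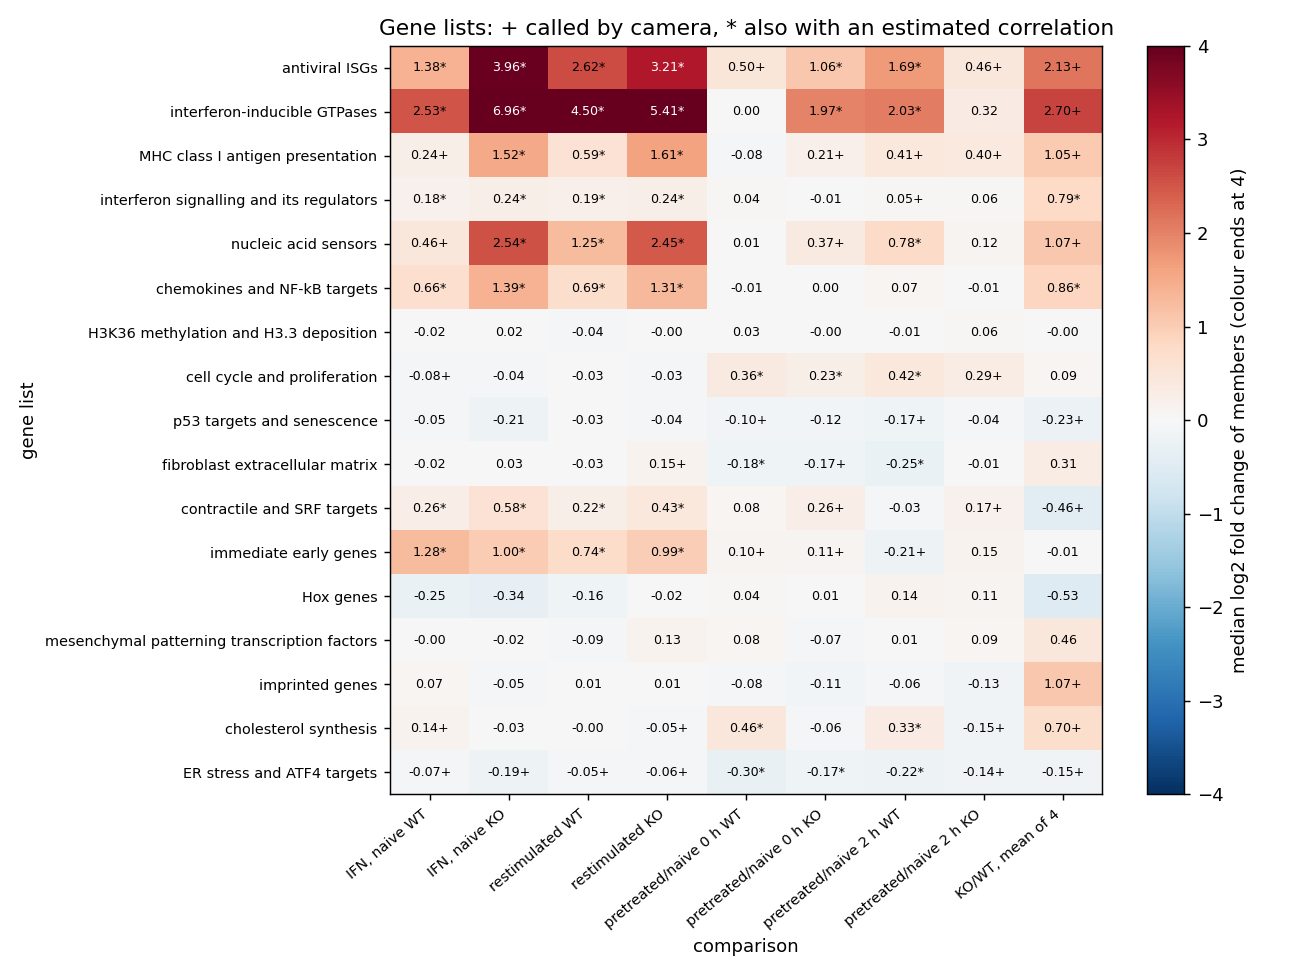
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis); colour and the printed number give the median, the colour ends at 4, a plus marks a camera call and an asterisk a call that also held with an estimated correlation. The antiviral list had a median of 1.38 for the naive response in WT and 3.96 in KO, the latter with 1 library at 2 h.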

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

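The genotype differences given first set KO against WT in the same contrast and were tested as such with edgeR or camera. Of the tests of explanations, those of restimulation and of sex, and those left open by the design, were chosen only after the result was seen, as were the leave-one-out ranges of slopes and their ratio and the exchanged library.

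The genotype difference of the naive interferon response held 2113 called genes. List medians were 2.21 for antiviral ISGs, 5.06 for interferon-inducible GTPases, 1.27 for MHC class I antigen presentation, 0.19 for interferon signalling and its regulators, 1.64 for nucleic acid sensors, 0.59 for chemokines and NF-kB targets, 0.32 for contractile and SRF targets, -0.061 for immediate early genes and -0.18 for cholesterol synthesis. Of these lists 3 lost their call, with adjusted p = 0.12 for contractile genes, 0.13 for immediate early genes and 0.16 for cholesterol synthesis with an estimated correlation. The genes named by size were Gm14446 8.84, Cxcl9 8.35, Fgl2 8.01, Oas1g 7.28, 2010002M12Rik 7.25, Misp 7.11, Slfn4 7.0 and Pou3f1 6.77 on the side of KO, and Rtn4rl1 -6.13, Ntf5 -5.43, Gm10125 -4.24, Ucn2 -3.61, 4732471J01Rik -3.42, Prr22 -3.12, Ccr7 -3.03 and Gpr160 -2.36 on the side of WT. Of these 16, 5 kept their call whichever library was left out, and values of Cxcl9, Fgl2, Oas1g, Rtn4rl1 and Ntf5, with a group at 0 counts, depend on the prior count. Without KO naive 0 h replicate 1, 3 lost the call (highest adjusted p = 0.058), and so did 10 without KO naive 0 h replicate 2 (0.34), 8 without WT naive 0 h replicate 1 (1.0), 5 without WT naive 0 h replicate 2 (0.14), 8 without WT naive 2 h replicate 1 (0.20) and 6 without WT naive 2 h replicate 2 (0.31). The lone KO naive 2 h library enters all of them and could not be left out.

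The genotype difference of the pretreatment effect at 0 h held 445 called genes (262 without KO naive 0 h replicate 2, 274 without KO pretreated 0 h replicate 2, 281 without WT naive 0 h replicate 1). List medians were 0.60 for antiviral ISGs, 1.5 for interferon-inducible GTPases, 0.29 for MHC class I antigen presentation, 0.33 for nucleic acid sensors, -0.12 for cell cycle and proliferation, 0.15 for fibroblast extracellular matrix, 0.22 for contractile and SRF targets, -0.55 for cholesterol synthesis, 0.14 for ER stress and ATF4 targets and -0.23 for cartilage and bone markers. Of these lists 6 lost their call, with adjusted p = 0.067 for MHC class I, 0.10 for sensors, 0.15 for cell cycle, 0.14 for matrix, 0.057 for contractile genes and 0.19 for ER stress with an estimated correlation. The matrix list had a mean of the other sign (-0.086), and ER stress had adjusted p = 0.055 without KO pretreated 0 h replicate 2 and 0.084 without the 3 libraries low in Rn45s. Named genes were Ifi44 2.97, Gbp9 2.89, Iigp1 2.54, Rtp4 2.08, A330076H08Rik 2.00, Acta1 1.95, Gbp3 1.83 and Ifih1 1.71, and Fbn2 -3.21, Cln3 -2.33, Trp63 -2.13, Il33 -2.10, Dcn -1.91, Ccl9 -1.79, Sprr1a -1.67 and Acer2 -1.51, of which 9 kept their call in every leave-one-out fit. Without KO naive 0 h replicate 1, 4 lost the call (highest adjusted p = 0.13), and so did 4 without KO naive 0 h replicate 2 (0.26), 5 without KO pretreated 0 h replicate 1 (0.20), 3 without KO pretreated 0 h replicate 2 (0.10), 7 without WT naive 0 h replicate 1 (0.35), 4 without WT naive 0 h replicate 2 (0.13), 5 without WT pretreated 0 h replicate 1 (0.20) and 4 without WT pretreated 0 h replicate 2 (0.25).

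The genotype difference of the pretreatment effect at 2 h held 1248 called genes (778 without WT naive 2 h replicate 1, 814 without KO pretreated 2 h replicate 1), with the same lone library. List medians were -1.24 for antiviral ISGs, -1.5 for interferon-inducible GTPases, -0.15 for MHC class I antigen presentation, -0.053 for interferon signalling and its regulators, -0.56 for nucleic acid sensors, -0.21 for cell cycle and proliferation, 0.32 for fibroblast extracellular matrix, 0.21 for contractile and SRF targets, 0.28 for immediate early genes and -0.50 for cholesterol synthesis. Of these lists 3 lost their call, with adjusted p = 0.36 for MHC class I, 0.10 for cell cycle and 0.14 for contractile genes with an estimated correlation. MHC class I also lost it without KO pretreated 2 h replicate 2 (adjusted p = 0.050), WT naive 2 h replicate 2 (0.16) or WT pretreated 2 h replicate 2 (0.10). Named genes were AI839979 6.40, Gm10125 4.44, Serpinb1b 4.17, Zfr2 3.23, Tnfsf18 3.17, Abca4 2.72, Ctnnd2 2.13 and Plxna4 2.06, and Ccrl2 -5.60, Immp2l -4.13, Sorl1 -3.79, Gm14446 -3.17, Arhgap26 -2.95, Oasl1 -2.57, Tmtc1 -2.46 and Ifit1 -2.41, of which 3 kept their call in every leave-one-out fit. Without KO pretreated 2 h replicate 1, 9 lost the call (highest adjusted p = 0.18), and so did 6 without KO pretreated 2 h replicate 2 (0.11), 8 without WT naive 2 h replicate 1 (0.26), 9 without WT naive 2 h replicate 2 (0.25), 8 without WT pretreated 2 h replicate 1 (0.19) and 4 without WT pretreated 2 h replicate 2 (0.16). AI839979 and Ccrl2 had a group at 0 counts.

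Antiviral genes responded more in KO, and the slope of pretreated minus naive at 2 h on that at 0 h was lower, 0.422 in KO (2995 genes, leave-one-out 0.373 to 0.447) against 0.702 in WT (0.488 to 0.774), the direction a pretreated library labelled KO naive 2 h would give. That is argued against, by a thin margin, by a ratio above 0.5, the bound set beforehand, in every leave-one-out fit (0.521 to 0.873), and by a slope 0.035 from 0 with a KO pretreated 2 h library in its place. That the single library alone carries the list's larger response is argued against by restimulation, which leaves it out. There antiviral genes rose a median 0.56 more in KO (leave-one-out 0.45 to 0.59), from a level 1.58 higher at pretreated 0 h. Of 62, 45 rose more in KO (28 called higher and 2 lower, camera p = 0.0094 with an estimated correlation). Ifit1 (7.10 in KO, 7.15 in WT), Usp18 (5.05, 5.63), Isg15 (3.73, 4.73), Oas1a, Oasl2 and Bst2 did not. Sizes in naive cells (list 2.21) cannot be told apart from a fault of that library. A difference between the cultures other than NSD2 cannot be told apart from an effect of its loss, since 9258 genes differed before interferon and no other culture of either genotype was labelled, so such an effect may stand only as a hypothesis.

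KO and WT differed at most genes. Of 60 splits of libraries, only the real one reached 10964 calls (next 7689, 2 libraries swapped). Chance differences between cultures were not tested. Embryos of different sex are argued against by Xist, at most 0.237 CPM, and by Y-linked genes in every library. These 4 were higher in KO, by log2 1.17 (Eif2s3y) to 1.62 (Kdm5d), which presence does not address, and WT cells without Y were not tested. Windows of 50 neighbouring genes held 3.3% of the variance beyond shuffled order. At an SD of 1.61 per gene this cannot decide on copy number, and 23 of 269 windows left the shuffled range. Origin of the cultures cannot be told apart from NSD2, since the labels name no embryo and Whsc1 itself differed by -0.18 at naive 0 h.

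Cell cycle genes were higher in pretreated libraries at 0 h, with a median of 0.36 in WT. The library low in Rn45s, WT naive 0 h replicate 1, is argued against as the cause, since the median without it was 0.37. Here and in other lists, washing or handling cannot be told apart from interferon, since the labels describe no mock-treated cells.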

How the results depend on the processing

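Leaving out Rn45s and Lars2, or the 3 libraries low in them, was chosen only after the result was seen. No value of a list or named gene reversed under any alternative run. Leaving out each library gave called counts of 2737 to 4443 for IFN response in WT naive, 4048 to 5109 for IFN response in KO naive, 10742 to 10896 for KO against WT, mean of 4 conditions, 7918 to 9322 for KO against WT, naive 0h, 2076 to 3401 for pretreated against naive at 0h in WT, 1897 to 3147 for pretreated against naive at 0h in KO, 2131 to 3154 for restimulation in WT pretreated, 3376 to 4431 for restimulation in KO pretreated, 2278 to 3517 for pretreated against naive at 2h in WT, 1674 to 2707 for pretreated against naive at 2h in KO, 1596 to 2188 for genotype difference of the naive IFN response, 262 to 500 for genotype difference of the pretreatment effect at 0h, 778 to 1335 for genotype difference of the pretreatment effect at 2h, 80 to 130 for gene list tests. Without KO naive 2 h, 5 comparisons have no value, so 80 list calls is a count over fewer tests. Without the 3 libraries low in Rn45s, the pretreatment effect at 0 h had 2172 calls in WT and its genotype difference 219, and fewer samples entered. With only the compared groups, pretreated against naive at 2 h in KO had 1646 calls, and the cause was not tested. With an estimated correlation 66 of the 125 list calls held, and 59 were lost. RLE, no filter, DESeq2 and Rn45s and Lars2 out of the counts kept each count within 1.5 times. Named genes lost their call in 640 of 22518 leave-one-out values and gained one in 66, and in 6 and 4 of 1543 with RLE, 16 and 19 of 1543 with no filter, 62 and 3 of 1379 with DESeq2, 45 and 10 of 1419 with the compared groups, 10 and 4 of 1541 without Rn45s and Lars2 and 144 and 6 of 1540 without the 3 libraries. List calls were lost in 16 of 4560 leave-one-out values and gained in 30. Groups with no count allow folds only as bounds from 3 counts at these depths.

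The replicate numbers do not pair the libraries, since none of 21 correlations of deviations passed 0.1 (-0.018 to 0.064). With the number as a replicate block, calls were 4525 for interferon in WT, 5314 in KO, 11079 for KO against WT, 2486 for the genotype difference and 126 for the lists, and no count moved by over 1.5 times. Within genotype the block gave 4467 and 5071 calls for interferon in WT and KO. Named genes lost their call in 7 of 1543 values and gained one in 22 with the block, and 18 and 24 of 1294 with the block within genotype.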

Other observations

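Genes of H3K36 methylation and H3.3 deposition, the process to which NSD2 belongs, had, in KO against WT over the 4 conditions, 12 of 26 members higher and 11 lower, or 12 and 11 adjusted over the list alone. The list was not called (median log2 change -0.0038, camera adjusted p = 0.82). Setd2, which encodes the enzyme that trimethylates H3K36, gave 1.08 ± 0.026 and Asf1b, a histone chaperone gene, 0.72 ± 0.035. Daxx, a chaperone gene of H3.3, rose with interferon by 0.62 ± 0.057 in naive WT cells and 2.94 ± 0.057 in naive KO cells (1 library at 2 h), a genotype difference of 2.33 ± 0.081 (edgeR adjusted p = 4.5e-19). Hoxb2 and Hoxb4 changed with interferon in naive KO cells by 2.33 ± 0.14 for Hoxb2 and 1.21 ± 0.22 for Hoxb4, and in pretreated KO cells by 2.18 ± 0.11 for Hoxb2 and 1.17 ± 0.17 for Hoxb4.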
